A study of Mus musculus with 9 samples.

How the data were processed

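RNA-seq counts per gene symbol of 9 mouse libraries were analysed: 3 of normal cerebellum, 3 of tumours with the empty vector and 3 of tumours with MycT58A. Per the labels' protocols, GFP-positive tumour regions were microdissected, total RNA was extracted with a NucleoSpin kit from the frozen pieces, and libraries followed the usual Illumina steps. The counts were deposited as whole numbers per gene symbol, and per the submitters' processing notes the tools were bcl2fastq, TopHat and edgeR, with the mm10 genome build. The versions of these tools, the read counter, the annotation and whether strand was used are not given in the sources used here. Reads of overlapping and antisense genes can therefore not be told apart, and genes with near-identical copies, such as ribosomal proteins, keratins and the H2 genes, are uncertain. Groups follow the source name and genotype labels, and replicates were numbered in the order of the samples, with no pairing between groups. The source name says cerebellum and the growth protocol speaks of cortex for the controls, so region markers were read in each control library.

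The table held 24444 gene symbols, of which 4711 had no count in any library. Positions come from GENCODE vM21 (mm10), in which 23695 of the symbols were found, and 569 of the 572 symbols on the fixed lists matched the table, 2 of them through a synonym. Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3) by group at a minimum count of 10 and a minimum total of 15, which left 15171. Counts were scaled by TMM, a quasi-likelihood model with 1 mean per group was fitted to all 9 libraries (glmQLFit, 6 residual degrees of freedom), and each pair of groups was compared with glmQLFTest. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and the SE of a log2 fold change is its size over the root of the F statistic. P-values measure the spread between these libraries and not the error of a single count. Each gene has 1 dispersion for all 9 libraries, so the p-values of a comparison also rest on the spread of the group not compared. A fold against a group without counts is a bound against a floor of 3 counts over the group, and groups with 1 to 3 counts have a ratio with an exact 95% interval. These floors and exact intervals cover counting error only. Principal components and list tests used log2 CPM with a prior count of 2.

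The 36 gene lists, of pathways, medulloblastoma genes and cell types, and the tests, comparisons, alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were the alternatives. Of the list genes, 9 stand on more than 1 list. Members past the threshold were also counted with p adjusted over the list alone. The named genes are the 5 engineered genes (Myc, Ctnnb1, Trp53, Pik3ca, Fabp7) and 6 region markers. To these come the 6 highest and 6 lowest log2 fold changes of each comparison among genes past the threshold, with at least 5 CPM in the higher group and values that do not overlap, leaving out predicted genes. From each list called by camera come the 2 members of smallest p, and 1 in the other direction where members passed both ways, and from each list not called with 1 to 3 members past the threshold those members. Against control, MycT58A tumours take list members only from those named in another comparison. Of the genes this rule names, 2 are not reported here. Pvt1, the Hox and keratin genes, genes high in a single library, sex-linked genes and the chromosomes were singled out after their values were seen.

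The alternatives were RLE scaling, library size alone, no low-count filter, a filter of 1 CPM in all libraries of a group, only the 2 groups compared in the fit, DESeq2 1.42.0, limma-voom, a test against a minimum fold of 1.5, and leaving out each library in turn. Weights per group (limma-voom) and thinning to the smallest library were added after the data were seen. Total counts per library were 16631523 to 30410089. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

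The gene test was tested on simulated counts with 200 changed genes and the real library sizes, in a single draw per setting. Before the changes, the 2 groups compared were both given the average of their real means. With each group's own spread, MycT58A against empty-vector tumours (15038 genes) recovered 0%, 2.99% and 25.8% of genes changed 1.5-, 2- and 4-fold, with 8 false calls among 27, and 10.7% of unchanged genes fell under an unadjusted p of 0.05. With the control spread in every group (15028 genes) it recovered 20.9%, 67.2% and 87.9%, with 8 false calls among 125. Empty-vector tumours against control recovered 0%, 1.49% and 19.7% with each group's own spread (15000 genes, 8 false calls among 22) and 8.96%, 50.7% and 92.4% with the control spread (15034 genes, 4 false calls among 105). MycT58A tumours against control made 0 calls by edgeR with each group's own spread (14973 genes; 0.542% of unchanged genes under an unadjusted p of 0.05) and recovered 19.4%, 58.2% and 95.5% with the control spread (14999 genes, 8 false calls among 123). Recovery was thus lower with each group's own spread than with the control spread in every group, and which group's spread lowered it was not tested. A list shifted 2-fold was called by camera in each of the 6 simulations, beside 0 of 31 other lists in 5 of them and 3 of 31 for MycT58A tumours against control with each group's own spread. Each gene was drawn independently, so these simulations cannot show how camera behaves where list members are correlated. In the data the estimated correlation was 0.94 for ribosome biogenesis, 0.601 for microglia and -0.0388 for PI3K/FOXO feedback genes.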

Results

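RNA was sequenced from mouse brain tissue in 9 libraries that fall into 3 groups of 3. One group is normal cerebellum of CD1-nude mice, which lack a thymus. The other groups are tumours of a WNT-medulloblastoma model, grown in CD1-nude hosts from implanted cells of Blbp-Cre mice with a floxed exon 3 of Ctnnb1, floxed Trp53 and the E545K form of Pik3ca. Loss of exon 3 stabilises beta-catenin, the protein product of Ctnnb1. The cells carried either a control vector (labelled EV, read here as empty vector) or MycT58A, a form of Myc in which the T58A change slows degradation of the protein. GFP-positive regions of the tumours were dissected. Total counts per library ranged from 16631523 in the library labelled empty-vector replicate 3 to 30410089 in MycT58A replicate 2. The control libraries held 24780263, 21761912 and 21154342 counts. Empty-vector replicates 1 and 2 held 29701006 and 22012375, and MycT58A replicates 1 and 3 held 28888621 and 24423717. Of 24444 gene symbols, 15171 had enough counts to be tested. Levels are CPM, counts divided by library sizes that were scaled with the TMM method, as means ± SD.

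The 5 engineered genes come first because they check the group labels. Myc (chromosome 15, 61985391 to 61990374, mm10) stood at 918, 859 and 727 CPM in the MycT58A libraries. In the empty-vector libraries it stood at 360, 19.9 and 762 CPM, and in the controls at 0.94, 1.59 and 32.0 CPM. The library labelled empty-vector replicate 3 therefore lay inside the range of the MycT58A libraries, and Myc did not separate the 2 tumour groups (log2 fold change 1.13 ± 1.37 SE, edgeR adjusted p = 0.592). Against control cerebellum Myc rose 33.1-fold in empty-vector tumours (edgeR adjusted p = 0.0253) and 72.5-fold in MycT58A tumours (edgeR adjusted p = 0.0118). Those folds rest on a control mean of 11.5 ± 17.8 CPM (SD, n = 3), which replicate 3 dominates. The call for empty-vector tumours ended without control replicate 1 or 2 or without the library labelled empty-vector replicate 3 (edgeR adjusted p = 0.06, 0.0699 and 0.0569). With only the 2 groups in the edgeR fit it also ended (adjusted p = 0.0611), so it passed under 15 of 19 alternatives. The labels do not say whether the MycT58A cDNA is mouse or human, and its reads are counted on Myc only where they align to the mouse gene. Pvt1, the noncoding gene beside Myc (chromosome 15, 62037986 to 62378096), was singled out after its values were seen. It stood at 96.4, 3.74 and 260 CPM in the empty-vector libraries, at 8.27, 7.91 and 4.86 CPM in the MycT58A libraries and at 5.39 to 7.04 CPM in the controls.

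**Figure D1:**
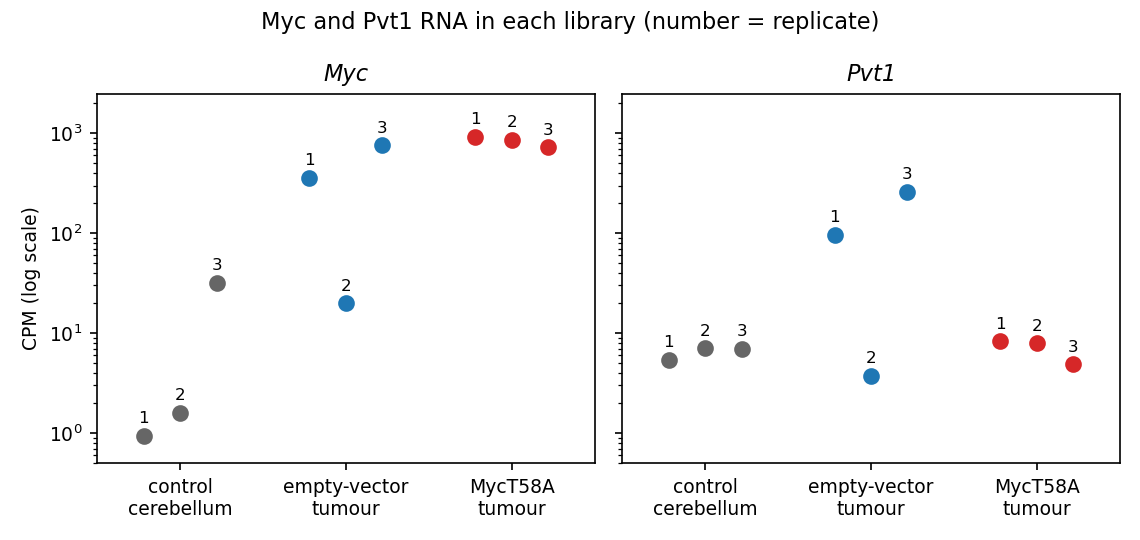
CPM of Myc (left) and Pvt1 (right) in each of the 9 libraries, on a log axis, with 1 point per library and its replicate number beside it. Myc spans 19.9 to 762 CPM in the empty-vector libraries and 727 to 918 CPM in the MycT58A libraries, while Pvt1 reaches 96.4 and 260 CPM in empty-vector replicates 1 and 3 alone.

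Ctnnb1 (chromosome 9, 120929216 to 120960507) rose 1.37-fold in empty-vector tumours, from 765 ± 55.4 to 1051 ± 34.8 CPM (SD, n = 3; edgeR adjusted p = 0.0426), and 1.35-fold in MycT58A tumours (edgeR adjusted p = 0.0465). Trp53 (chromosome 11, 69580359 to 69591873) fell 2.15-fold in empty-vector tumours, from 14.8 ± 2.25 to 6.88 ± 2.19 CPM (SD, n = 3; edgeR adjusted p = 0.0162). In MycT58A tumours it stood at 9.22 ± 2.01 CPM (SD, n = 3; edgeR adjusted p = 0.0858 against control). Pik3ca (chromosome 3, 32397671 to 32468486) passed edgeR in no comparison with all 9 libraries (adjusted p = 0.811 and 0.104 in empty-vector and MycT58A tumours against control), at 132 ± 1.9, 123 ± 63.7 and 82 ± 17 CPM (SD, n = 3) in control, empty-vector and MycT58A libraries. Fabp7 (chromosome 10, 57784881 to 57788450), which encodes the brain lipid-binding protein whose promoter drives the Cre line, fell 8.55-fold in empty-vector tumours (edgeR adjusted p = 0.0109) and 10.7-fold in MycT58A tumours (edgeR adjusted p = 0.00629). Its level was 124 ± 22 CPM in controls, 14.4 ± 3.18 in empty-vector and 11.5 ± 9.12 in MycT58A tumours (SD, n = 3). Ctnnb1 lay close to the threshold: without any 1 of the 3 control or the 3 MycT58A libraries its edgeR adjusted p was 0.0666 to 0.12 for empty-vector and 0.0745 to 0.139 for MycT58A tumours. It passed under 9 and 8 of 19 alternatives, with adjusted p from 0.000382 to 0.633 and from 0.000848 to 0.655 by edgeR, DESeq2 or limma-voom. The Trp53 call in empty-vector tumours ended without control replicate 3 (edgeR adjusted p = 0.0679). It passed under 16 of 19 alternatives, with adjusted p from 0.0016 to 0.107 by edgeR, DESeq2 or limma-voom. Without empty-vector replicate 2 the fall of Trp53 in MycT58A tumours passed (edgeR adjusted p = 0.0351). That fall also passed with only the 2 groups in the edgeR fit, with DESeq2 and with limma-voom weights per group (adjusted p = 0.0189, 0.037 and 0.00756), so under 4 of 19 alternatives, with adjusted p from 0.00756 to 0.278. Without empty-vector replicate 1 the falls of Pik3ca passed in empty-vector (edgeR adjusted p = 0.0371) and in MycT58A tumours (edgeR adjusted p = 0.0125). In MycT58A tumours Pik3ca also passed with only the 2 groups in the edgeR fit (adjusted p = 0.00337) and with limma-voom weights per group (adjusted p = 0.00107), so under 3 of 19 alternatives, with adjusted p from 0.00107 to 0.293. Neither Ctnnb1, Trp53, Pik3ca nor Fabp7 differed between the tumour groups, with edgeR adjusted p from 0.263 to 0.943. Counts per gene symbol cannot show a deleted exon or the E545K change.

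One label calls the control tissue cerebellum and another speaks of cortex, so region markers were read in the 3 control libraries, here as CPM on total counts. Gabra6 and Cbln3, which mark cerebellar granule neurons, stood at 741 ± 186 and 1350 ± 333 CPM (SD, n = 3). Pcp2, which marks Purkinje cells, stood at 172 ± 30.4 CPM (SD, n = 3). The forebrain gene Emx1 had 0 counts, where 3 counts make 0.142 CPM in the least deep control, and Tbr1 stood at 0.729 ± 0.189 CPM (SD, n = 3). The median over 15 granule neuron genes was 408, 449 and 362 CPM in the 3 controls, against 0.868, 0.505 and 0.685 CPM over 14 forebrain cortex genes.

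The first principal component of log2 CPM held 72.2% of the variance and set the tumours apart from cerebellum, and the second held 11%. The empty-vector libraries lay far apart from each other. Over the 500 genes that varied most among the tumours, the distance between MycT58A libraries was 23.7 to 31.5 log2 units, that between empty-vector libraries 89.9 to 111.2, and that between a library of each group 84.1 to 99.1. The median SD of a gene was 0.64 log2 units in empty-vector tumours, 0.20 in MycT58A tumours and 0.17 in controls, and 86.1% of genes had a larger SD in the empty-vector than in the MycT58A group.

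**Figure D2:**
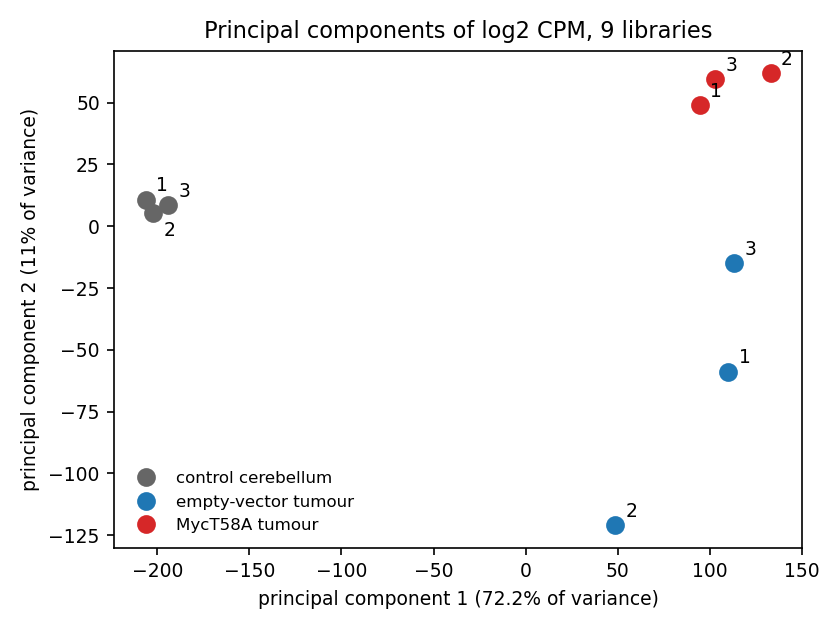
First and second principal components of log2 CPM (72.2% and 11% of the variance), 1 point per library with its replicate number. The 3 control libraries and the 3 MycT58A libraries each form a tight cluster, and the 3 empty-vector libraries spread along the second component.

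What MycT58A adds to the WNT model is the question of the comparison between MycT58A and empty-vector tumours. The genotype labels do not say whether the 3 tumours of a group came from separate preparations of cells. If they did not, the libraries of a group are not independent, and p-values would be too small. Limma camera called 5 lists of growth genes higher and 6 lists lower in MycT58A tumours, among them microglia and interferon genes, though few members passed singly and 0 of the 11 calls stayed with an estimated correlation (adjusted p = 0.756 or 0.794). With fry 0 of the 11 stayed as well. The gene with the firmest difference was Pou3f4, a POU transcription factor of neural development, at 120 ± 26.5 CPM in MycT58A and 0.251 ± 0.111 CPM in empty-vector tumours (SD, n = 3), a 465-fold rise. The replication factor Mcm5 rose 3.13-fold, from 114 ± 46.9 to 355 ± 43.1 CPM (SD, n = 3), and the ribosomal protein gene Rpl13 rose 2.4-fold. Cd68, a lysosomal protein of macrophages, fell 3.16-fold, from 23.1 ± 3.11 to 7.31 ± 1.53 CPM (SD, n = 3), and Pdgfrb, a receptor of pericytes and fibroblasts, fell 5.43-fold. In all, 1259 genes changed (8.3% of those tested; 498 higher and 761 lower in MycT58A tumours; edgeR quasi-likelihood test, adjusted p under 0.05). In the simulation with each group's own spread, 8 of 27 calls of this comparison were false, so the threshold was not held there.

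Among the largest rises after Pou3f4 (log2 fold change 8.86 ± 0.45 SE, edgeR adjusted p = 0.000256) were Foxa2, a forkhead factor of the floor plate and endoderm, at 188-fold (edgeR adjusted p = 0.0117), and Emilin3, an extracellular glycoprotein, at 62.7-fold (edgeR adjusted p = 0.0175). The signalling adaptor Stap1 rose 57.7-fold (edgeR adjusted p = 0.00606), the matricellular gene Smoc2 42.8-fold (edgeR adjusted p = 0.0215) and the insulin receptor substrate Irs4 38.5-fold (edgeR adjusted p = 0.0471). Those 5 stood at 0.217 to 0.542 CPM in empty-vector tumours and at 21.1 to 41.9 CPM in MycT58A tumours. The largest falls were those of the basal keratins Krt5 (870-fold, edgeR adjusted p = 0.0242) and Krt14 (272-fold, edgeR adjusted p = 0.042), Lad1 (480-fold, edgeR adjusted p = 0.0424), Inmt (435-fold, edgeR adjusted p = 0.0328), Lrtm1 and Hand2. Lrtm1 had 1236 counts in empty-vector and 3 in MycT58A tumours, a ratio of 465 with a 95% counting interval of 159 to 2260 (edgeR adjusted p = 0.0433). Hand2, a transcription factor of heart and sympathetic neurons, fell 257-fold from 43.8 ± 18.4 CPM (SD, n = 3; edgeR adjusted p = 0.00936). Many of these folds rest on 1 empty-vector library. Of the 58 named genes that passed, 26 moved more than 1.5-fold when 1 library was left out, 25 of them most with an empty-vector library, and 13 became smaller. Without replicate 3 Krt5 was 145-fold lower, Krt14 22.8-fold, Lad1 17.7-fold, Mef2c 3.68-fold and Cdkn1a 3.49-fold. Without replicate 2 Inmt was 58.1-fold lower, Ocln 8.57-fold, Ifit1 8.25-fold and Tapbp 3.46-fold, and Lrtm1 stood at 8.01, 42.2 and 0.51 CPM in the empty-vector libraries. Without replicate 1 Aqp1 was 37.3-fold lower, Nkd2 3.87-fold and Plk2 3.15-fold. The other 13 became larger. Without replicate 2 Smoc2 was 105-fold higher, Clic6 19-fold, Lhx2 13.6-fold, Zic1 13.2-fold, Agmat 10.7-fold, Slc1a3 7.88-fold and Map2 5.49-fold. Without replicate 3 Emilin3 was 103-fold higher and Pdk1 6.58-fold, without replicate 1 Irs4 153-fold, and without MycT58A replicate 1 Hand2 was 411-fold lower. Foxa2 stood at 0, 0.595 and 0.0567 CPM in the empty-vector libraries, and the single count of Neurod6 there lay in replicate 1.

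Camera called 5 lists higher in MycT58A tumours, all of them lists of growth genes, while few of their members passed singly. For 25 ribosome biogenesis genes that MYC activates, the median fold was 1.94 and 0 rose (camera adjusted p = 5.35e-06; 0 adjusted over the list alone). At unadjusted p under 0.05 edgeR had 7 of them, DESeq2 called 5 and limma-voom 2. Nop56 and Nolc1, both nucleolar, stood at 521 ± 59.4 against 178 ± 109 CPM and at 454 ± 6.55 against 189 ± 104 CPM (SD, n = 3), with edgeR adjusted p = 0.0639 and 0.0808. For 20 ribosomal protein genes the median fold was 1.79 and 1 rose, or 9 adjusted over the list alone (camera adjusted p = 1.7e-06). That gene was Rpl13 (edgeR adjusted p = 0.0222), and Rpl18 stood at 1.9-fold (edgeR adjusted p = 0.063); reads of such genes can be shared with processed pseudogenes, so their levels are uncertain. For 21 nucleotide and one-carbon genes the median fold was 1.86 and 1 rose, or 7 adjusted over the list alone (camera adjusted p = 1.23e-05). Mthfd2, a mitochondrial folate enzyme, rose 2.14-fold (edgeR adjusted p = 0.0442), and the purine enzyme Paics stood at 2.38-fold (edgeR adjusted p = 0.0509). Of 22 DNA replication genes 2 rose, Mcm5 (edgeR adjusted p = 0.0226) and the clamp Pcna, 2.66-fold (edgeR adjusted p = 0.0389), or 4 adjusted over the list alone (camera adjusted p = 5.35e-06). Of 20 mitosis genes 1 rose, Nusap1, 2.99-fold (edgeR adjusted p = 0.0455), and 0 adjusted over the list alone. Kif11, the spindle motor, stood at 3.04-fold (edgeR adjusted p = 0.0694; list by camera adjusted p = 0.000515). With an estimated correlation between members all 5 calls ended, at camera adjusted p = 0.756 with an estimated correlation, or 0.794 for mitosis. Without empty-vector replicate 2 the mitosis call also ended (camera adjusted p = 0.0842). That library had the lowest medians: relative to controls, nucleotide genes stood at 2.02, 0.62 and 3.23 log2 units in the empty-vector libraries and 2.96 to 3.2 in the MycT58A libraries, and ribosome biogenesis genes at 2, 0.67 and 2.66 against 2.78 to 2.83.

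Camera called 6 lists lower in MycT58A tumours. Of 18 microglia and macrophage genes 6 fell and 0 rose, or 17 adjusted over the list alone (median 4.07-fold lower, camera adjusted p = 4.24e-07). Cd68 (edgeR adjusted p = 0.0134) and the lipid receptor Trem2, 4.81-fold (edgeR adjusted p = 0.0312), were among them. Of 15 pericyte and fibroblast genes 4 fell, or 10 adjusted over the list alone (median 5.07-fold lower, camera adjusted p = 0.000515), among them Pdgfrb (edgeR adjusted p = 0.0227) and Pdgfra, 3.13-fold (edgeR adjusted p = 0.0424). Of 18 interferon response genes 3 fell, or 10 adjusted over the list alone (median 3.93-fold lower, camera adjusted p = 7.44e-06). Ifit1 fell 16.3-fold (edgeR adjusted p = 0.0286) and Isg15 14.2-fold (edgeR adjusted p = 0.033). Of 14 MHC class I and antigen processing genes 1 fell, Tapbp, the chaperone tapasin, 5.65-fold (edgeR adjusted p = 0.0242), or 9 adjusted over the list alone (camera adjusted p = 0.00173). The class I heavy chain gene H2-D1 stood at 13.4 ± 1.66 CPM in MycT58A and 116 ± 145 CPM in empty-vector tumours (SD, n = 3; edgeR adjusted p = 0.0535). H2 genes are near-identical copies whose reads can be misassigned. Of 13 endothelial genes 0 passed, over all genes or adjusted over the list alone (median 2.18-fold lower, camera adjusted p = 0.0175), with Tek at 4.6-fold lower (edgeR adjusted p = 0.0766) and Tie1 at 3.11-fold lower (edgeR adjusted p = 0.119). At unadjusted p under 0.05 edgeR had 4, DESeq2 called 2 and limma-voom 0. Of 13 PI3K/FOXO feedback genes 0 passed, or 5 fell adjusted over the list alone (camera adjusted p = 0.0387), with Foxo1 at 2.45-fold lower (edgeR adjusted p = 0.0509) and Irs1 at 1.94-fold lower (edgeR adjusted p = 0.059). Here edgeR had 7 at unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0. All 6 calls ended at camera adjusted p = 0.756 with an estimated correlation, or 0.794 for endothelium.

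Of these lower lists, the microglia and interferon calls stayed at the preset correlation with any 1 library left out, and the other 4 depended on single libraries. Relative to controls, the median of the MHC class I list was 2.23 log2 units higher in empty-vector replicate 2 and -0.24 and 0.21 in replicates 1 and 3, and that of the interferon list 2.67, 0.01 and 0.62. In MycT58A libraries these medians were -0.26 to -0.54 and -0.63 to -1.77. The median of the microglia list was 1.42, 2.09 and 0.15 in the empty-vector libraries and 0.13, -1.54 and -0.57 in the MycT58A libraries. Empty-vector replicate 3 thus lay near MycT58A replicate 1. Without empty-vector replicate 2 the calls of endothelium, MHC class I, pericytes and fibroblasts, and PI3K/FOXO feedback ended (camera adjusted p = 0.364, 0.0583, 0.0767 and 0.0767). The endothelium call also ended without replicate 3 of either tumour group (camera adjusted p = 0.0652 and 0.0766), and the PI3K/FOXO call without empty-vector replicate 1 or MycT58A replicate 3 (camera adjusted p = 0.144 and 0.0609).

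**Figure D3:**
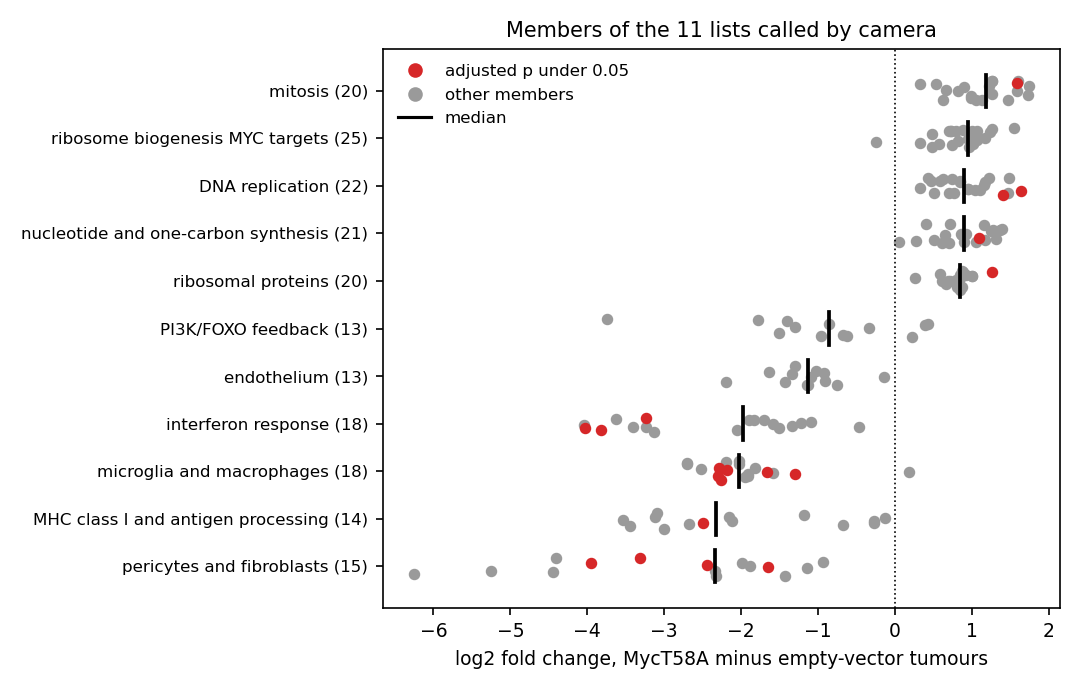
Log2 fold change between MycT58A and empty-vector tumours of each tested member of the 11 lists that camera called, 1 point per gene, red where the edgeR adjusted p was under 0.05, with the median of each list as a bar. Medians lie between 0.84 and 1.18 for the 5 lists called higher and between -2.34 and -0.86 for the 6 called lower.

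Camera called none of the other 21 tested lists between the tumour groups, although members of several passed. Of 25 WNT/beta-catenin targets 2 fell, or 4 with 1 that rose adjusted over the list alone (limma camera adjusted p = 0.308). They were the cyclin gene Ccnd1, 2.77-fold (edgeR adjusted p = 0.0261), and the pathway inhibitor Nkd2, 6.7-fold (edgeR adjusted p = 0.0316). Of 19 p53 targets 3 fell, or 4 with 1 that rose adjusted over the list alone, namely Trp53inp1, 4.38-fold, the cell-cycle inhibitor Cdkn1a, 13.8-fold, and Plk2, 5.83-fold, with edgeR adjusted p from 0.0242 to 0.0469. Cdkn1a stood at 1180 CPM in the library labelled empty-vector replicate 3 and at 132 CPM or less in each other library. Of 18 serine synthesis and ATF4 genes 2 rose and 1 fell, or 6 and 1 adjusted over the list alone. Psat1, an enzyme of serine synthesis, rose 2.67-fold (edgeR adjusted p = 0.0214), Aldh18a1 rose 2.35-fold and Cebpb fell 4.23-fold (edgeR adjusted p = 0.023 and 0.027). The kinase gene Pdk1, on the glycolysis and the hypoxia list, rose 3.97-fold, Mxi1 on the hypoxia list rose 1.79-fold and the hexokinase gene Hk1 fell 2.05-fold (edgeR adjusted p = 0.0344, 0.0433 and 0.049). Adjusted over the list alone, 1 glycolysis gene rose and 1 fell, and 3 hypoxia genes rose and 1 fell. On the polyamine list Sat1, a catabolic enzyme, fell 3.15-fold and Agmat rose 6.73-fold, both at edgeR adjusted p of 0.0318 or less.

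Among genes of neural and stromal identity, the rhombic lip genes Lhx2 and Zic1 rose 6.67- and 7.29-fold (edgeR adjusted p = 0.0313 and 0.034), and adjusted over the list alone 2 rose and 2 fell. Zic2, on the granule neuron list, rose 1.61-fold, and Map2, a neuronal microtubule protein on the synapse list, rose 3.41-fold (edgeR adjusted p = 0.0448 and 0.0418), with 1 and 3 that rose adjusted over the list alone. On the astrocyte list the glutamate transporter Slc1a3 rose 4.58-fold and the connexin Gja1 fell 2.81-fold (edgeR adjusted p = 0.0313 and 0.0208). On the list of oligodendrocyte progenitors Lhfpl3 fell 4.54-fold beside Pdgfra (edgeR adjusted p = 0.0423). On the forebrain list Mef2c fell 10.5-fold (edgeR adjusted p = 0.0327), and Neurod6 had 24 counts in MycT58A and 1 in empty-vector tumours, a ratio of 21.3 (95% counting interval 3.47 to 874; edgeR adjusted p = 0.0252). For these 3 lists the counts adjusted over the list alone were the same. Of 15 blood-brain barrier genes 3 fell, or 7 adjusted over the list alone: Itm2a 7.63-fold, the amino acid transporter Slc7a8 3.08-fold and the tight junction gene Ocln 13.4-fold (edgeR adjusted p = 0.0104, 0.0144 and 0.0394). On the list of leaky endothelium the growth factor Vegfb rose 2.86-fold and Plpp1 fell 3.91-fold, and on the choroid plexus list Clic6 rose 9.81-fold and the water channel Aqp1 fell 64.6-fold, with edgeR adjusted p from 0.00879 to 0.0379. Of 22 matrix and invasion genes the hyaluronan receptor Cd44 rose 1.99-fold, and the integrin Itga5 fell 4.63-fold and the protease Plau 3.44-fold (edgeR adjusted p = 0.0442, 0.0144 and 0.0305; 1 rose and 4 fell adjusted over the list alone). Bpgm, on the red blood cell list of 3 tested genes, fell 2.23-fold (edgeR adjusted p = 0.0104). No member of the SHH, neural stem, photoreceptor, Purkinje, mature oligodendrocyte, neutrophil or lymphocyte lists passed edgeR over all genes; adjusted over the list alone 1 photoreceptor and 2 neutrophil genes fell. In these 7 lists edgeR had 2, 4, 3, 1, 1, 2 and 1 genes at unadjusted p under 0.05, DESeq2 called 1, 1, 1, 1, 1, 2 and 0, and limma-voom called 2 neural stem genes and 0 in the others.

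Median and test differ in sign for the neural stem list (median -0.30, camera up), the progenitor list of oligodendrocytes (median 0.82, camera down) and the hypoxia list (median -0.03, camera up), and the mean of the SHH list was -0.40 against a median of 0.28. Leaving out 1 library started further calls by limma camera. These were barrier endothelium lower without empty-vector replicate 1 (adjusted p = 0.0332), and glycolysis and hypoxia higher without replicate 3 (adjusted p = 0.00124 and 0.0322). Serine synthesis was called higher without MycT58A replicate 1 or 3 (camera adjusted p = 0.0436 and 0.0258), and granule neuron and synapse genes higher without MycT58A replicate 2 (camera adjusted p = 0.00234 and 0.00215).

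The number of genes that differed between the tumour groups varied with the libraries in the fit and with the tool. The count of 1259 fell to 34 with only the 6 tumour libraries in the edgeR fit, all of them among the 1259, and rose to 3446 with DESeq2. It was 70, 58 and 36 without MycT58A replicates 1, 2 and 3, and 363, 311 and 361 without control replicates 1, 2 and 3. Without empty-vector replicates 1, 2 and 3 it was 1924, 2565 and 3977. Leaving out a MycT58A library ended 53 to 56 of the 58 calls of named genes and leaving out a control library 37 to 42; Pou3f4 passed under all 19 alternatives, with adjusted p up to 0.0295. The split of 498 higher and 761 lower genes became 301 and 938 on library size alone and 884 and 629 with limma-voom. Of all tested genes 31.8% had values that did not overlap between the tumour groups. The share of 10% by chance with 3 against 3 libraries holds only for groups of equal spread. The median SD was 0.64 log2 units in empty-vector and 0.20 in MycT58A tumours, so no excess can be read from it.

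How tumours of the WNT model differ from normal cerebellum is the question of the comparison between empty-vector tumours and control. Limma camera called 9 lists higher, among them WNT targets and mitosis, and 6 lists of cerebellar neurons and glia lower, and 0 of these 15 calls stayed with an estimated correlation (adjusted p = 0.343 for WNT targets and 0.509 for mitosis and the 6 lower lists). With fry, which does not set a list against other genes, all 15 stayed (fry adjusted p = 2.4e-05 for WNT targets and 0.000778 for mitosis). Fzd10, a WNT receptor gene, rose 130-fold, from 1.81 ± 0.433 to 236 ± 49.6 CPM (SD, n = 3), and Notum, a secreted WNT inhibitor, rose 131-fold, from 1.54 ± 0.473 to 203 ± 24 CPM (SD, n = 3). Foxm1, a transcription factor of mitosis, rose 28.6-fold. Ppp1r17, a phosphatase inhibitor of Purkinje cells, fell 410-fold, from 251 ± 11.2 to 0.602 ± 0.474 CPM (SD, n = 3), and the synaptic vesicle gene Syp fell 156-fold. Without empty-vector replicate 2 Ppp1r17 was 729-fold lower. In all, 8643 genes changed (57% of those tested; 4652 higher and 3991 lower in the tumours; edgeR adjusted p under 0.05). In the simulation with 200 changed genes and each group's own spread, 8 of 22 calls of this comparison were false. With so few changed genes, that share cannot be carried over to the 8643 calls. Leaving out 1 library ended at most 7 of 58 calls of named genes.

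The largest rises were those of genes without a single count in the controls, for which only a lower bound can be given against a floor of 3 counts over the group. The homeobox genes Tlx1 and Barx1 were at least 1700-fold and at least 700-fold higher (edgeR adjusted p = 0.00695 and 0.000281). Fst, the activin-binding protein follistatin, Rspo4, an R-spondin that enhances WNT signalling, and Gykl1 were at least 560-, 440- and 430-fold higher (edgeR adjusted p = 0.00142, 0.00249 and 0.00138). Lrrc15 had 4950 counts in the tumours and 1 in the controls, a ratio of 4820 (95% counting interval 864 to 190000; edgeR adjusted p = 0.0105). Lrrc15 stood at 0.377, 0.934 and 279 CPM in the empty-vector libraries and was 33.7-fold higher without replicate 3. Tlx1 stood at 161, 0.934 and 28.7 CPM, Rspo4 at 34, 1.19 and 19.1 CPM, Barx1 at 52.5, 10.5 and 22.1 CPM, Fst at 9.59, 57.2 and 5.5 CPM and Gykl1 at 6.61, 6.67 and 54.9 CPM. Among the largest falls, Ldoc1, the interneuron factor Pax2, the receptor gene Gpr12, the glycine transporter Slc6a5 and Lingo4 had no count in the tumours and were at least 320-, 220-, 220-, 200- and 180-fold lower, with edgeR adjusted p from 0.000467 to 0.00264. Nwd2 had 3129 counts in the controls and 3 in the tumours, a ratio of 1070 (367 to 5200; edgeR adjusted p = 2.2e-05), with 0.0685, 0.0425 and 0 CPM in the empty-vector libraries.

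Camera called 9 lists higher in empty-vector tumours than in cerebellum. Of 25 WNT/beta-catenin targets 23 rose (median 40.6-fold, limma camera adjusted p = 7.22e-09; adjusted p = 0.343 with an estimated correlation), with edgeR adjusted p = 1.19e-05 for Fzd10 and 1.28e-05 for Notum. All 20 mitosis genes rose (median 53-fold, camera adjusted p = 7.22e-09), among them Foxm1 (edgeR adjusted p = 5.66e-05) and the kinesin Kif20a, 28.2-fold (edgeR adjusted p = 0.000131). Of 22 DNA replication genes 21 rose (median 7.96-fold, camera adjusted p = 9.69e-08), among them E2f1 and Gins2, 20.5- and 22.4-fold. All 20 ribosomal protein genes rose (median 4.26-fold, camera adjusted p = 6.87e-08), with Rplp0 at 9.75-fold and Rpl18 at 4.76-fold. Of 25 ribosome biogenesis genes 23 rose (median 3.96-fold, camera adjusted p = 2.63e-05), with the helicase Ddx21 at 9.24-fold and the nucleolar methyltransferase Fbl at 6.61-fold. Of 21 nucleotide and one-carbon genes 18 rose (median 5.6-fold, camera adjusted p = 4.94e-05), with Mthfd2 at 7.46-fold and thymidylate synthase, Tyms, at 21.2-fold. Of 18 serine synthesis and ATF4 genes 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00211). Asparagine synthetase, Asns, rose 5.21-fold and Pycr1 208-fold, and Ddit3 fell 2.12-fold (edgeR adjusted p = 0.0428). Of 22 matrix and invasion genes 16 rose (median 8.85-fold, camera adjusted p = 4.94e-05; adjusted p = 0.265 with an estimated correlation), with Itga5 at 27.7-fold and the gelatinase Mmp2 at 179-fold. Of 15 pericyte and fibroblast genes 9 rose (camera adjusted p = 0.032), with the collagen Col3a1 at 62-fold and lumican, Lum, at 19.8-fold; that call ended without empty-vector replicate 2 (camera adjusted p = 0.302). Leaving out 1 empty-vector library lowered Pycr1 to 87.4-fold and Tyms to 14-fold (replicate 3) and Lum to 12.5-fold (replicate 1). The other calls of this paragraph ended at camera adjusted p = 0.509 with an estimated correlation, or at 0.646 for ribosome biogenesis and 0.622 for nucleotide synthesis and for pericytes.

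Camera called 6 lists lower, all of cerebellar neurons and glia. All 15 granule neuron genes fell (median 183-fold lower, camera adjusted p = 2.72e-08), among them the splicing factor Rbfox1, 79.2-fold, and Zic2, 4.9-fold. All 15 Purkinje cell genes fell (median 230-fold lower, camera adjusted p = 2.72e-08), among them Ppp1r17 (edgeR adjusted p = 2.21e-05) and the calcium channel Itpr1, 35.3-fold (edgeR adjusted p = 7.6e-05). Of 20 synapse genes 18 fell and 1 rose (median 128-fold lower, camera adjusted p = 2.72e-08). Syp and the kinase Camk2a, 71.9-fold, were among the falls, and Stx1a, a syntaxin of vesicle release, rose 4.25-fold (edgeR adjusted p = 0.00648). Of 15 astrocyte genes 13 fell (median 15.4-fold lower, camera adjusted p = 0.000289), with Slc1a3 at 66-fold (113-fold without empty-vector replicate 2) and Fgfr3 at 6.42-fold. Of 15 oligodendrocyte genes 13 fell, or 14 adjusted over the list alone (median 43.3-fold lower, camera adjusted p = 2.48e-05), with Tspan2 at 26.6-fold and Gjc3 at 51.9-fold. Of 10 oligodendrocyte progenitor genes 7 fell and 1 rose (median 20.7-fold lower, camera adjusted p = 0.0071). Cacng4 fell 14.2-fold and the lineage factor Olig2 55.2-fold, and the growth factor receptor Pdgfra rose 4.3-fold (edgeR adjusted p = 0.00254). Each of the 6 calls ended at camera adjusted p = 0.509 with an estimated correlation. Setting members with 3 or fewer counts in a group at the bound of the floor changed no list median of this or the other comparison with control at 2 decimals.

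**Figure D4:**
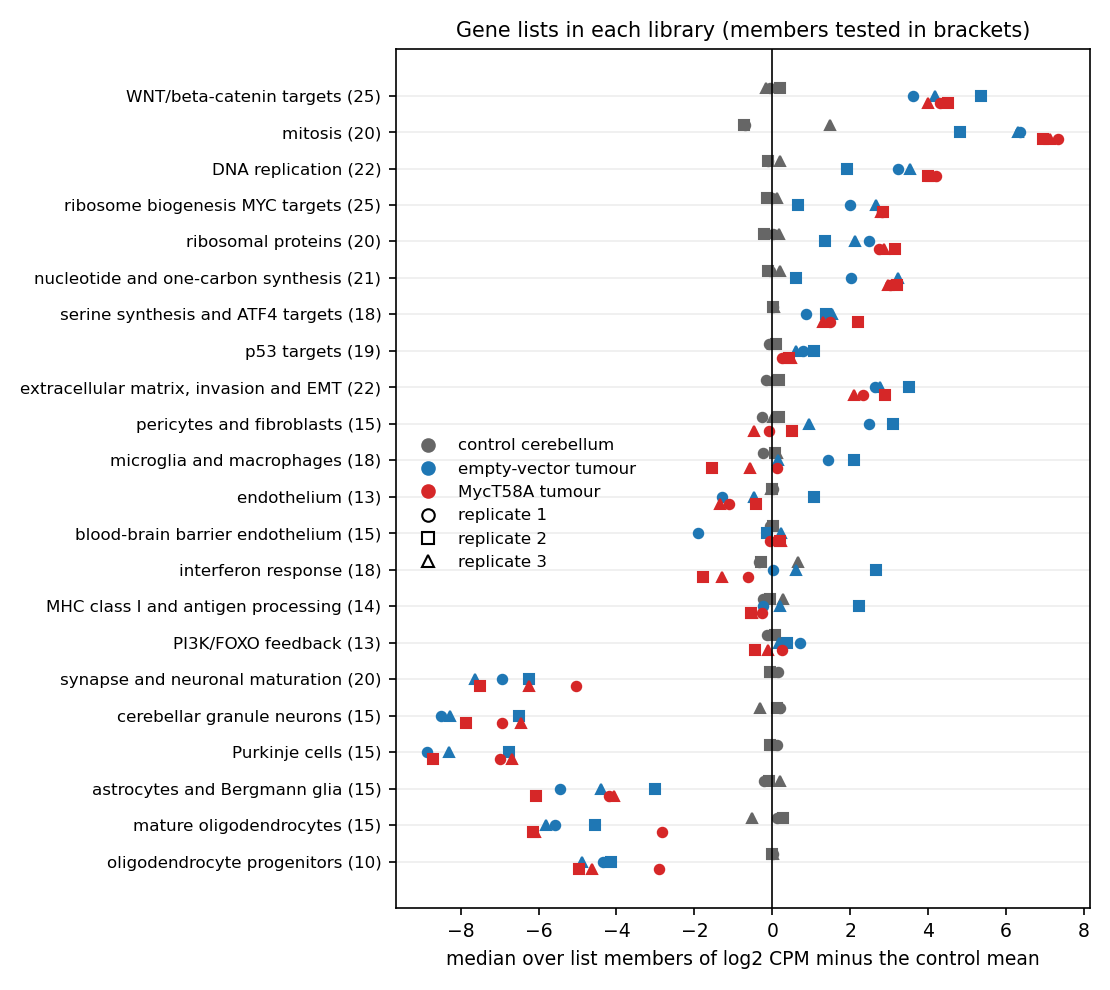
Median over the tested members of 22 lists of log2 CPM minus the mean of the 3 control libraries, 1 point per library, with colour for the group and shape for the replicate. WNT targets stand 3.61 to 5.35 log2 units above control in all 6 tumours, and empty-vector replicate 2 has the lowest medians of the mitosis, DNA replication, ribosome and nucleotide lists and the highest of the MHC class I and interferon lists among the tumours.

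Members of lists that camera did not call also changed in empty-vector tumours. Of 18 microglia genes 9 rose and 0 fell (camera adjusted p = 0.0502). That list passed without control replicate 2 or 3 (adjusted p = 0.0403 and 0.039), without the library labelled empty-vector replicate 3 (0.00198) and without MycT58A replicates 1, 2 or 3 (0.0387, 0.0313 and 0.0471). Of 14 MHC class I genes 7 rose, or 3 adjusted over the list alone, and of 18 interferon genes 4 rose and 1 fell, or 3 and 1. Of 17 neural stem genes 9 rose and 2 fell, of 13 rhombic lip genes 7 rose and 4 fell, of 12 SHH genes 4 rose and 2 fell, and of 10 forebrain genes 3 rose and 5 fell. Of 19 p53 targets 8 rose and 3 fell, of 17 hypoxia genes 6 rose, and of 20 glycolysis genes 2 rose and 7 fell, or 2 and 6 adjusted over the list alone. Of 13 PI3K/FOXO genes 5 rose and 3 fell, of 15 barrier genes 4 rose and 4 fell, of 12 leaky endothelium genes 5 rose and 1 fell, and of 13 endothelial genes 0 passed edgeR, 0 at unadjusted p under 0.05 and 0 by DESeq2 against 3 by limma-voom. Without empty-vector replicate 1 camera called MHC class I and neural stem genes higher (adjusted p = 0.0193 and 0.0375), and without replicate 3 glycolysis lower (adjusted p = 0.0287). Both polyamine genes that passed rose, ornithine decarboxylase, Odc1, 5.08-fold and spermidine synthase, Srm, 4.88-fold (edgeR adjusted p = 0.000372 and 0.00477). Aqp1 and Sostdc1 of the choroid plexus list rose 510- and 323-fold, Npr3 of the photoreceptor list 172-fold, the neutrophil genes S100a9 and S100a8 15.3- and 4.44-fold, and Cd4 14.3-fold, with edgeR adjusted p from 0.000751 to 0.0251. Of these, Npr3 was 11.4-fold higher without empty-vector replicate 1 and Sostdc1 53.9-fold and Cd4 3.14-fold without replicate 2, S100a9 3.47-fold and Srm 2.89-fold without replicate 3, and Aqp1 1510-fold without control replicate 2. Npr3 lies in a block of chromosome 15, Dnajc21 to Drosha, whose genes were all raised in empty-vector replicate 1. Slc4a1, the anion exchanger of red cells, had 114 counts in the controls and 2 in the tumours, a ratio of 58.6 (15.9 to 490; edgeR adjusted p = 0.00692), with 0, 0.0425 and 0.0567 CPM in the empty-vector libraries. Medians and means differ in sign for the polyamine list (-0.22 and 0.26) and the barrier list (-0.21 and 0.11), and the endothelial median of 0.24 goes against a downward camera direction.

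The same question was asked of the MycT58A tumours against the same 3 control libraries. Fzd10 and Notum rose 143- and 140-fold, to 260 ± 23.6 and 216 ± 66.3 CPM (SD, n = 3; edgeR adjusted p = 1.38e-05 and 1.52e-05). Foxm1 rose 57-fold, to 89.1 ± 7.27 CPM, and Rplp0 17.9-fold, to 5790 ± 947 CPM (SD, n = 3; edgeR adjusted p = 3.09e-05 and 3.38e-05). Ppp1r17 fell 130-fold, to 1.92 ± 0.645 CPM, and Syp 60.4-fold, to 21.8 ± 7.93 CPM (SD, n = 3; edgeR adjusted p = 3.35e-05 and 3.19e-05). In all, 9438 genes changed (62.2% of those tested; 4732 higher and 4706 lower; edgeR adjusted p under 0.05). Leaving out 1 library ended at most 4 of 53 calls of named genes.

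Among the largest rises, Fst, Rspo4, Irs4 and the homeobox genes Tlx2 and Phox2a had no count in the controls and were at least 870-, 570-, 490-, 270- and 270-fold higher, with edgeR adjusted p from 0.000943 to 0.0257. Foxa2 had 3269 counts in the tumours and 1 in the controls, a ratio of 2820 (95% counting interval 505 to 111000; edgeR adjusted p = 0.000249). Among the largest falls, Ccdc63 and the cation channel Trpc7 had no count in the tumours and were at least 160- and 150-fold lower (edgeR adjusted p = 0.000213 and 5.72e-05). Ldoc1 and the synaptotagmin Syt10 had 1 count each in the tumours, ratios of 1080 (193 to 42700) and 1060 (190 to 41900; edgeR adjusted p = 0.00042 and 5.52e-05). Sycp1, a protein of the synaptonemal complex, fell 614-fold and Cntnap5b 554-fold (edgeR adjusted p = 2.01e-05 and 0.000241). Of the 53 named genes that passed, 9 moved more than 1.5-fold with 1 library left out, each to a larger fold. The only count of Foxa2 in the controls lay in replicate 2, and those of Ldoc1 and Syt10 in MycT58A tumours in replicates 1 and 3. Cntnap5b stood at 0.036, 0 and 0.171 CPM in the MycT58A libraries, and its fold was largest without replicate 3. Without control replicate 3 Myc was 666-fold higher.

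Of the 25 WNT/beta-catenin targets 21 rose, or 22 with 1 that fell adjusted over the list alone (median 19-fold, limma camera adjusted p = 3.47e-08; adjusted p = 0.433 with an estimated correlation). All members rose in the lists of mitosis (20 genes, median 108-fold), DNA replication (22, 16.9-fold), ribosomal proteins (20, 7.51-fold), ribosome biogenesis (25, 6.96-fold) and nucleotide synthesis (21, 8.28-fold), with camera adjusted p from 5.81e-09 to 2.64e-07. Examples were Nusap1, 43.3-fold, Mcm5, 25.1-fold, Gins2, 46.2-fold, Rpl13, 8.13-fold, Ddx21, 18.7-fold, Fbl, 13.3-fold, Mthfd2, 15.9-fold, and Tyms, 34.8-fold. Of 18 serine synthesis and ATF4 genes 13 rose and 1 fell (camera adjusted p = 0.000629), with Aldh18a1 at 7.02-fold, Asns at 8.73-fold and Ddit3 at 3.84-fold lower. Of 22 matrix and invasion genes 15 rose (camera adjusted p = 0.000629), with Cd44 at 12.9-fold and Mmp2 at 121-fold. All 15 granule neuron and all 15 Purkinje cell genes fell (medians 149- and 167-fold lower, camera adjusted p = 2.64e-07 and 1.59e-07), among them Rbfox1, 65.9-fold, and Itpr1, 61.8-fold. Of 20 synapse genes 19 fell, among them Camk2a, 125-fold, and Stx1a rose 5.46-fold (camera adjusted p = 1.92e-07). Of 15 astrocyte genes 13 fell, of 15 oligodendrocyte genes 14 and of 10 oligodendrocyte progenitor genes 8 (camera adjusted p = 8.45e-05, 0.000102 and 0.00378), with Fgfr3 at 6.16-fold, Tspan2 at 21.7-fold, Gjc3 at 34.4-fold (73.7-fold without MycT58A replicate 1), Cacng4 at 8.17-fold and Lhfpl3 at 19.9-fold. These calls ended at camera adjusted p = 0.468 with an estimated correlation, at 0.519 for ribosome biogenesis, 0.484 for nucleotide synthesis and oligodendrocytes, and 0.433 for the matrix list. With fry all 14 lists called by camera stayed.

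Of the lists camera did not call in MycT58A tumours, 1 microglia gene rose and 4 fell of 18, and 2 MHC class I genes rose and 2 fell of 14, or 1 rose and 0 fell adjusted over the list alone. Of 18 interferon genes 1 rose and 5 fell, or 1 and 2 adjusted over the list alone. Of 13 endothelial genes 3 fell, the receptor genes Tek, 11.7-fold, and Flt1, 5-fold, and the phosphatase Ptprb, 5.42-fold (edgeR adjusted p = 0.00283, 0.00425 and 0.00791). Of 15 pericyte genes 3 rose and 2 fell, or 3 and 1 adjusted over the list alone. Clic6, Sostdc1 and Aqp1 of the choroid plexus list rose 14.1-, 91.1- and 7.89-fold, or 2 of the 3 adjusted over the list alone (edgeR adjusted p = 0.00274, 0.0116 and 0.0447). Csf3r of neutrophils fell 3.94-fold, Rom1 of photoreceptors 6.89-fold, and Bpgm and Slc4a1 of red cells 2.65- and 18.1-fold, with edgeR adjusted p from 0.000156 to 0.022. Slc4a1 stood at 0.252, 0 and 0 CPM in the MycT58A libraries, so its fold rests on the counts of replicate 1. Without control replicate 2 Aqp1 was 23.2-fold higher, and without MycT58A replicate 1 Csf3r was 6.02-fold lower. Of 17 neural stem genes 7 rose and 3 fell, of 13 rhombic lip genes 6 and 4, of 12 SHH genes 4 and 2, of 10 forebrain genes 3 and 6, and of 9 polyamine genes 3 and 3. Of 17 hypoxia genes 8 rose and 2 fell, of 20 glycolysis genes 5 and 7, of 19 p53 targets 5 and 3, of 13 PI3K/FOXO genes 2 and 5, of 15 barrier genes 5 and 7, and of 12 leaky endothelium genes 4 and 0 by edgeR. The neural stem list passed without control replicate 3, empty-vector replicate 3 or MycT58A replicate 2 (camera adjusted p = 0.0492, 0.0463 and 0.0489), and the hypoxia list without MycT58A replicate 3 (camera adjusted p = 0.0399). Medians and means differ in sign for the glycolysis (0.09 and -0.28), barrier (0.12 and -0.79), PI3K/FOXO (0.11 and -0.40) and photoreceptor lists (-0.59 and 0.01). That a gene passed in 1 tumour group against control and not in the other does not show a difference between the tumours, which the direct comparison tests.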

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

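The weights per group and the thinning were chosen after the data were seen. Among the counts of genes changed, that between MycT58A and empty-vector tumours (1259) depended most on the processing. It was 34 with only the 2 groups in the fit, 3446 with DESeq2 (466 genes without an adjusted p), 295 at a minimum fold of 1.5 and 449 with weights per group (mean weight 2.54 for controls, 0.213 for empty-vector and 1.84 for MycT58A libraries). With 1 library left out it ran from 36 to 3977: 70, 58 and 36 without MycT58A replicates 1, 2 and 3, 363, 311 and 361 without the control replicates, and 1924, 2565 and 3977 without the empty-vector replicates. The other settings gave 861 to 1513 genes. The share of higher genes was 39.6%, against 24.3% on library size alone, which moved the median of all genes from -0.04 to -0.17 log2 units, and 58.4% with limma-voom. The counts against control stayed within 1.5 times of 8643 and 9438 under every alternative run, at 6954 to 10186 and 8012 to 10860 with 1 library left out. Camera called 11, 15 and 14 lists for MycT58A against empty-vector tumours, empty-vector tumours against control and MycT58A tumours against control, and 0 in each with an estimated correlation. With fry, which does not set a list against other genes, 0, 20 and 23 were called, and 0, 15 and 14 of the camera calls stayed. With 1 library left out camera called 6 to 13, 14 to 17 and 14 to 15, with 6 without empty-vector replicate 2. RLE scaling and library size alone kept all of these camera calls. Named genes stayed on their side of the threshold in 182 cases under RLE scaling, 164 with limma-voom, 143 at the minimum fold and 124 with 2 groups, where 4, 19, 44 and 56 calls ended, and in 168 with DESeq2, where 11 more passed. Values that did not pass changed sign for Ctnnb1 between the tumours (-0.043 to 0.021 log2 units with 1 library left out; above 0 without empty-vector replicate 2 or MycT58A replicate 3), for Fabp7 between the tumours (-0.75 to 0.23; above 0 without MycT58A replicate 2), and for Pik3ca in empty-vector tumours against control (-0.61 to 0.17; above 0 without empty-vector replicate 2 or 3). Fewer samples are part of the fits with 2 groups or 1 library left out. They cannot alone account for the moves between the tumour groups, since leaving out an empty-vector library raised that count. The spread also differed, with a median SD of 0.64, 0.20 and 0.17 log2 units in empty-vector, MycT58A and control libraries. Otherwise the cause was not tested. Thinned to the smallest library, 1132 genes changed between the tumours. No paired analysis was possible because the labels give no replicate numbers.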

Other observations

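These tests were chosen after the result was seen: those of a mislabelled library, of the chromosome 15 flanks and Pvt1, of raised blocks and chromosome shifts, of cerebellar and host-cell shares, of Xist, and of WNT targets and mitosis genes in control replicate 3. The intervals and upper limits of medians given below come from a bootstrap, which redraws the genes of a list or region. They treat these genes as independent and do not measure the spread between libraries. The Hox and keratin genes were singled out after their values were seen. Hox genes, which pattern the body axis behind the cerebellum, were near 0 in the cerebellum libraries, where their summed level was 0.0817 to 0.354 CPM. In the empty-vector libraries it was 101, 34.4 and 135 CPM, and in the MycT58A libraries 9.28, 11.2 and 7.5 CPM. Of the Hox genes, 11 had enough counts to be tested, which they reached through tumour libraries, and edgeR called all 11 higher in empty-vector tumours and 5 in MycT58A tumours than in control. Compared directly, edgeR called 2 of the 11 lower in MycT58A than in empty-vector tumours, DESeq2 5 and limma-voom 3. Without empty-vector replicates 1, 2 and 3 edgeR called 1, 6 and 3 lower. None stayed called without any 1 of the MycT58A libraries, though 0 of 11 folds lay above 0 there. Without empty-vector replicate 3, 4 of 11 folds lay above 0. A difference of the family between the tumour groups is therefore not shown. Against control, all 11 also rose in empty-vector tumours under RLE scaling and library size alone, while 8 did with DESeq2 or limma-voom. Without control replicates 1, 2 and 3 edgeR called 7, 7 and 8, without empty-vector replicate 3 it called 7, and without MycT58A replicates 1, 2 and 3 it called 9, 10 and 9. In MycT58A tumours 9 of 11 were called without empty-vector replicate 3.

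Each empty-vector tumour library held high genes that no other library shared. Counting genes at 20 CPM or more and at least 8-fold above every other library, replicates 1, 2 and 3 had 31, 60 and 53, and each MycT58A library 0. In replicate 2 the protease inhibitor A2m stood at 29900 CPM (at most 272 elsewhere), vitronectin, Vtn, at 2240, the lipase relative Pnliprp1 at 2080, periostin, Postn, at 2010 and the class I gene H2-K1 at 583. Replicate 3 had the collagen gene Col1a2 at 1810 CPM, the p53 target Cdkn1a at 1180, the desmosome gene Dsp at 874 and Lrrc15 at 279. Of 16 keratin genes tested 5 were among its 53 genes, and summed keratins stood at 532 CPM there against 34.9 and 76.2 CPM in replicates 1 and 2. Replicate 1 had the microRNA processing gene Drosha at 2600 CPM, the mitochondrial gene Ndufb9 at 2040 and the glutamate receptor gene Grik1 at 1430. Drosha and Ndufb9 lie in the 2 raised blocks of chromosome 15 described below. H2-K1 lies in the stretch of chromosome 17 that held raised windows in replicate 2.

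Myc RNA differed between the empty-vector libraries (360, 19.9 and 762 CPM). A lower share of tumour cells in replicate 2 is argued against, since WNT targets there stood above replicates 1 and 3 (median log2 difference 0.98, 95% interval 0.5 to 1.91) where Myc stood at -4.71. A MycT58A tumour like the other 3 under the label of replicate 3 is argued against by its mean distance to them, 96 against at most 31.5 among them (a ratio of 3.05), but it lay 89.9 and 111.2 from empty-vector replicates 1 and 2, a range that holds those 3 distances (92.1, 99.1 and 96.8), so a MycT58A tumour of another kind stays open. A gain of chromosome 15 across both sides of Myc is argued against for replicate 3 alone, by 25 genes within 5 Mb with a median log2 ratio to replicate 2 of -0.23 (-0.73 to 0.18), while in replicate 1 a block of 17 genes beside Myc (57.87 to 59.66 Mb) was raised 12.6-fold and a gain stays open. A candidate explanation is transcription from the endogenous locus, since Pvt1 in replicates 1 and 3 was at least 11.6 times its level in the other tumour libraries, but the idea came from these values, DNA was not measured, and a focal change of copies or of regulation cannot be told apart.

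For the 1259 genes that differed between the tumour groups, a different share of normal cerebellum is argued against, because granule neuron markers stood at no more than 1.13% of control in a tumour library (upper limit 1.75%), and 99.3% of the changed genes (489 of 498 higher, 761 of 761 lower) differed by more than such a share can make. Depth is argued against by the 89.9% of the count (1132 genes) found with equal depth, and chromosome-wide shifts as the bulk of it by the 936 calls, or 74.3%, kept (1256 in all) with chromosome medians removed. A lower share of host cells in the MycT58A pieces stays open for the host-cell genes: the medians for endothelium, microglia and pericytes were all lower (-1.12, -2.03 and -2.34). Set against the MycT58A mean, microglia lay above endothelium in each of the 3 empty-vector libraries. The log2 differences were 2.22 (95% interval 2.05 to 2.58), 0.55 (-0.04 to 0.96) and 0.35 (0.01 to 0.58) in replicates 1, 2 and 3. Arguing against this share would have needed intervals without 0 in all 3 libraries. The 10 splits of 6 libraries are too few for a share under 0.05: the real split was the 1 split with as many genes (1259, 8643 and 9438 in the 3 comparisons, with 0 by edgeR as the highest other in each). Each other split mixes the 2 groups, so differences between them widen the spread and leave few calls. The 0 therefore tells nothing about chance. Open stays a biological effect of MycT58A beside differences between single tumours, of which the wider spread of the empty-vector group is a measured part. Whether the MycT58A tumours arose separately cannot be told from the genotype labels.

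Control replicate 3 held Myc at 32 CPM, 5.27% of the tumour mean, and 18, 11, 3 and 2 counts of the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d, against 0 or 1 in the other controls; these are genes that 6 of 6 tumour libraries also held. RNA of these tumours as the source of Myc is argued against by WNT targets, at an excess of -0.226% of their lowest tumour level (-1.11 to 0.314) where Myc needs 3.35%, with Fzd10 at 1.49 CPM against 8.86 needed, while other tumour genes, at a median of 0.196% of the tumour mean (0.0519 to 2.66), leave it open on their own. Open stays RNA of other dividing cells, since all 20 mitosis genes were higher there than in replicates 1 and 2 (medians 3.31 and 0.56 CPM, median log2 ratio 2.17, 95% interval 1.44 to 2.88), a pattern seen before it was tested. A general rise of cell-cycle genes stays open too: DNA replication genes were at a median log2 ratio of 0.3 (0.15 to 0.49), under a bound of 0.5 set before, but that bound was wrong because their 6.43 CPM in the other controls hides a small share. No biological explanation was tested, since the labels give the 3 controls no difference.

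In empty-vector replicate 1, 35 windows of 15 neighbouring genes were raised more than 4-fold, all 35 on chromosome 15 (highest log2 ratio 3.69); replicate 2 had 10 such windows, on chromosome 17 (highest 3.59), and the other tumour libraries 0. They form 2 blocks: Dnajc21 to Drosha (10.45 to 12.94 Mb), with 18 of 18 genes raised at a median of 12.9-fold, and Derl1 to Trib1 (57.87 to 59.66 Mb), with 17 of 17 at 12.6-fold. Derl1 stood at 1480 CPM and the sterol enzyme Sqle at 1230. Extra copies are a candidate explanation, and more transcription of the same copies cannot be told apart because DNA was not measured. Whole chromosomes also shifted: 6 by more than 0.3 log2 units in replicate 1 (chromosome 8 by -0.87 and chromosome 3 by 0.72, shuffled positions at most 0.21), with chromosome 14 by 0.61 in replicate 2 and chromosome 19 by -0.62 in replicate 3. A permutation test of gene positions gave p = 0.001, the smallest that 1000 shuffles can give, in each tumour library, though MycT58A libraries shifted by at most 0.18. Each shift was taken against the median of the other tumour libraries, so a shift that the MycT58A libraries share can be partly hidden. Between the tumour groups the median log2 fold change was 0.42 on chromosome 8 and -0.31 on chromosome 3. Different karyotypes are a candidate explanation, and regulation cannot be told apart for the same reason. Of 597 genes on chromosome 8, 12.7% were higher in MycT58A tumours, against 3.29% elsewhere, with 11% against 3.56% on chromosome 19, 8.5% against 3.4% on chromosome 2 and 0.574% against 3.98% on chromosome 3.

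Y-linked genes in empty-vector replicate 2 stood at 4.13% to 11.4% of the other empty-vector libraries. Female host cells as most of that library are argued against by Xist, at 4.14% of its control mean. Xist was low in every tumour library (0.177 to 1.81 CPM), so it tells nothing more about the tumour cells of replicate 2. A lost or silent Y chromosome is a candidate that was not tested, and other sources stay open. In the same library the 10 windows on chromosome 17 cover 33.96 to 34.74 Mb, where 12 of 24 genes were raised at least 2-fold. Of these 24 genes 4 are on the MHC class I list.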
